A study of Mus musculus with 6 samples.

How the data were processed

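Transcript levels were measured on 6 Agilent arrays with 2 colours, 3 of mouse embryos from eggs activated with cycloheximide and 3 from eggs activated with strontium chloride. Per the labels' protocols, the embryos were kept for 60 h in culture, and mRNA equivalent to 25 embryos was amplified in 2 rounds and labelled with Cy3. On every array the other channel held the same commercial mouse reference RNA, amplified in 1 round and labelled with Cy5. No array had the dyes exchanged, so a dye effect on a probe stays in each ratio but is shared by both groups. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

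The deposited table holds log10 ratios of the channels, 1 column per array, for 22132 probes. Agilent Feature Extraction is named in the submitters' processing notes; its version, its background settings and its dye normalization are not given in the sources used here. The deposited log10 ratios lie between -2 and 2, with values exactly at these limits, so a ratio beyond 100-fold was reduced to that size. Values of exactly 0 (471 to 755 probes per array) are taken as ratios that were not set, which the table itself does not state. For probes at 0 on only some arrays, they nevertheless stayed in the main fit, the gene averages and the list tests as log2 ratios of 0. Differences of such probes can rest partly or wholly on unset values. The array medians of the deposited log10 values were -0.0538, -0.0517 and -0.0313 for cycloheximide and -0.0580, -0.0602 and -0.0389 for strontium. The values are not centred by gene. No spot intensities were used, so signal over background is unknown, and the number of arrays limits the precision.

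The direction of the ratio is not stated with the values. It was taken as likely that they are reference over embryo, from the dyes in the labels and from Feature Extraction's convention of red over green. Each value was therefore turned in sign and multiplied by 3.32 to give log2 of embryo over reference. The check planned beforehand asked that an oocyte gene list lie above both a fibroblast and an adult organ list on every array. The oocyte median lay above the fibroblast median on 6 of 6 arrays, but above both on only 4 of 6. The check was thus met in part. Dppa3 and Col1a1 had been looked at before it was run. If the direction were the opposite, every sign given for a level or a difference would turn.

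Probes were named through the platform annotation supplied for the table: 6249 probes had 1 gene, 9389 had several and were not named, and 6494 were unlisted. Of the probes with 1 gene, 6179 matched the mouse gene table (assembly GRCm38.p6) by gene ID, and 0 symbols needed an update. That table was used for names alone. The sources name no genome build, so no coordinates are given. The 211 probes at exactly 0 on all 6 arrays were left out, which left 21921 probes, 6152 of them with 1 gene and representing 4742 genes. This exclusion was not part of the plan: it was made after a first fit of all probes had been seen, and the fit of all probes is given among the alternatives.

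The difference between groups (cycloheximide minus strontium) was tested per probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without further normalization, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. For gene lists, the probes of a gene were averaged and camera was run with a correlation of 0.01 over 30 lists, 26 of genes and 4 of markers of other cells, with an estimated correlation and fry as alternatives. Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6 prepared the values, and matplotlib 3.10.9 drew the plots. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, among probes with 1 gene and in each direction, the 12 probes with the largest difference among those past the threshold whose groups do not overlap, with gaps filled by the smallest unadjusted p. Of each list it took the member with the smallest p, and up to 4 members to describe a direction. Since 0 probes passed, all 24 probes of the first part were chosen by p among probes with 1 gene, so probes with no or several gene names can have a smaller p. A choice by p tends to pick sizes that are too large.

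The fit was tested on simulated data with the real means and spread of the 21921 probes. At the adjusted threshold it recovered 0% of the planted log2 changes of 1 and 22% of those of 2, with 0 false calls. At an unadjusted p under 0.05 it recovered 69% and 87%. With 0.25 times the real spread it recovered 83% and 99%, with 10 false calls. The simulated noise was independent between probes and had the same spread on every array, unlike that of the real arrays. These rates and counts of false calls may therefore not hold for the real arrays. In the simulation for lists, the 44 ribosomal protein genes were shifted by a log2 of 1. That list was found and 0 other lists were called. No smaller shift and no smaller list was planted. The simulation therefore cannot say whether shifts like the real list medians, which lie between -0.34 and 0.21, would be found. Its noise was independent between genes, unlike that of real arrays.

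The alternatives were a replicate block, quantile normalization, centring of each array on its median, leaving out the lowest 25% of probes by mean, probes with values on all arrays (21067), trend and robust moderation, array weights, averaged probes, an adjusted p of 0.10, a minimum of 1.5-fold, and leaving out each array in turn. After the data were seen, a correction for position along the probe numbers, the removal of the first 5 lines of probe numbers, and the fits of all probes were added. Replicate numbers are shared by the groups in the labels. The sources do not tie them to a shared culture or day, and the plan set no replicate block for the main fit. Deviations from the group means of arrays with the same number correlated at 0.056, 0.379 and 0.501 for numbers 1, 2 and 3. Cycloheximide 1 and strontium 2, which have unlike numbers, correlated at 0.457, above the pairs of numbers 1 and 2. Deviations sum to 0 within a group, so these values are not independent. A pairing by number is thus neither shown nor excluded, and the block is given only as an alternative.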

Results

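Mouse eggs arrested at metaphase of the second meiotic division were activated without sperm, and the resulting parthenogenetic embryos were profiled after 60 h in culture. Cycloheximide blocks protein synthesis and activates eggs without a rise in calcium. Strontium chloride makes the egg release calcium repeatedly. Cytochalasin D, which blocks the extrusion of the polar body, was given with both. Each group held 3 arrays, every array had the same reference RNA in its other channel, and 21921 probes were compared. The title of the series sets the question: whether the lack of a calcium signal at activation alters gene expression later in development. Levels are log2 ratios of embryo over reference as mean ± SD (n = 3 arrays per group), and differences are cycloheximide minus strontium with their SE.

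No transcript passed the test between the groups. Of probes with 1 gene, those with the smallest p that lay higher after cycloheximide included Zbtb25, a zinc finger gene, Adam10, a membrane protease, and Ier2, an immediate early gene. Zbtb25 was at 0.55 ± 0.25 after cycloheximide and -2.04 ± 0.32 after strontium, a difference of 2.59 (SE 0.24). Adam10 was at 0.79 ± 0.09 and -0.55 ± 0.04, a difference of 1.34 (SE 0.16). Among those lower after cycloheximide were Svil, which encodes an actin-binding protein, at -1.33 ± 0.23 and 0.13 ± 0.15, and Tmsb4x, which encodes an actin-sequestering peptide, at 0.69 ± 0.25 and 1.83 ± 0.28.

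By limma, 0 probes were higher and 0 lower at an adjusted p of 0.05, and the lowest adjusted p was 0.365. At an unadjusted p under 0.05 there were 811 higher and 508 lower probes, 6.02% of those tested, where chance alone gives 1096 probes. The arrays of the groups did not overlap for 2578 probes, or 11.8%, against 10% by chance. The 95% interval at the median SE extended 0.71 on the log2 scale to each side of the difference, or 1.63-fold, so smaller changes could not be told from 0 for a typical probe even before adjustment. With array weights, an alternative whose estimate stopped before it converged, 224 probes were higher and 135 lower.

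The other genes on the higher side were Bod1l (difference 1.82), Ly75 (1.60), Ier2 (2.09), Pnn (2.74), Akap13 (1.15), Lyst (0.98), Smad1 (1.63), Polr1a (1.79), Septin11 (1.47) and Scamp1 (1.18). Smad1 encodes a mediator of BMP signalling, and Polr1a the largest subunit of RNA polymerase I. Pnn was at the lower limit of the ratio on 1 array, so its size is uncertain. Different probes of a gene did not always go the same way. The other probe of Zbtb25 differed by -0.30 and that of Ier2 by -0.03. Of the 5 probes of Bod1l, another differed by 1.08, and the remaining values were -0.33, 0.20 and -0.09.

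On the lower side lay Svil (difference -1.46), Gramd1a (-1.64), Rnf144b (-0.90), Tmsb4x (-1.14), Gadl1 (-0.90), Crk (-1.55), Rsrc1 (-1.05), Srr (-1.06), Cdc40 (-0.99), Casz1 (-0.95), Zranb1 (-0.69) and Siae (-1.46). Crk encodes an adaptor of signalling at the membrane, and Cdc40 a splicing factor. The other 4 probes of Gadl1 lay on the opposite side, between 0.17 and 0.61, and its probes averaged 0.18. The other probes of Svil differed by -0.76, -0.15, -0.08 and 0.00. Rsrc1 was at exactly 0 on 1 array. Of these 12 probes, 9 lie among the first 5 lines of probe numbers, where 11.3% of probes were lower at an unadjusted p under 0.05 against 1.87% elsewhere. Without array 3 of cycloheximide these shares were 17.1% and 12.7%. Of the 12 higher probes, 1 (Smad1) lies there. Higher probes at an unadjusted p under 0.05 crowded on other lines, picked here after their values were seen. Line 21 held 16 higher and 0 lower probes. Ly75 and Scamp1 lie on line 89 (12 higher, 1 lower), Akap13 on line 19 (14 and 2) and Pnn on line 16 (11 and 0). The median deviation of array 3 of cycloheximide from each probe's mean ran from -0.34 on line 2 to 0.43 on line 24.

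**Figure D1:**
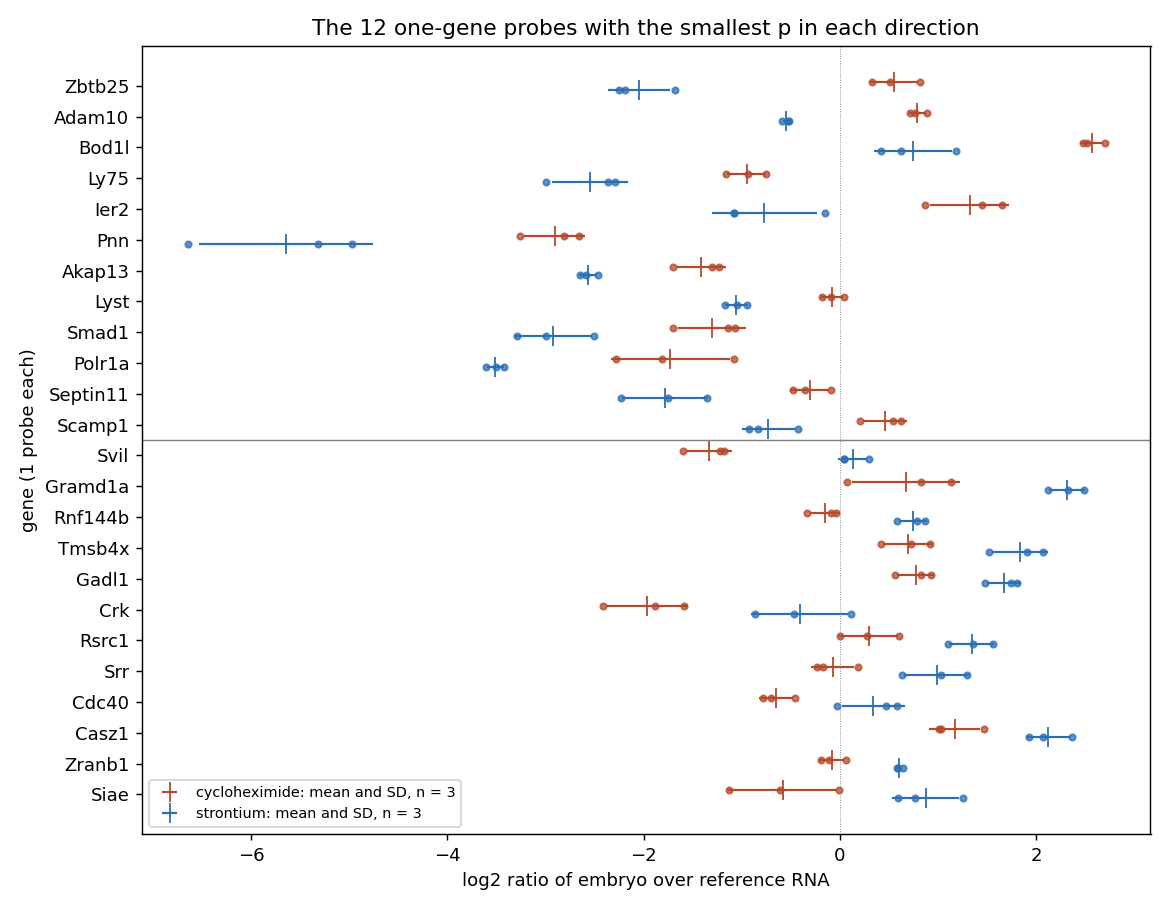
Log2 ratio of embryo over reference RNA (horizontal axis) for the 12 probes with the smallest p in each direction among those with 1 gene, higher after cycloheximide above the line and lower below it. Dots are single arrays, ticks the mean and bars the SD of 3 arrays. The groups do not overlap for any of the 24 probes, which a choice by the smallest p favours. For Rsrc1 1 array is at exactly 0. The lowest limma adjusted p is 0.365.

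**Figure D2:**
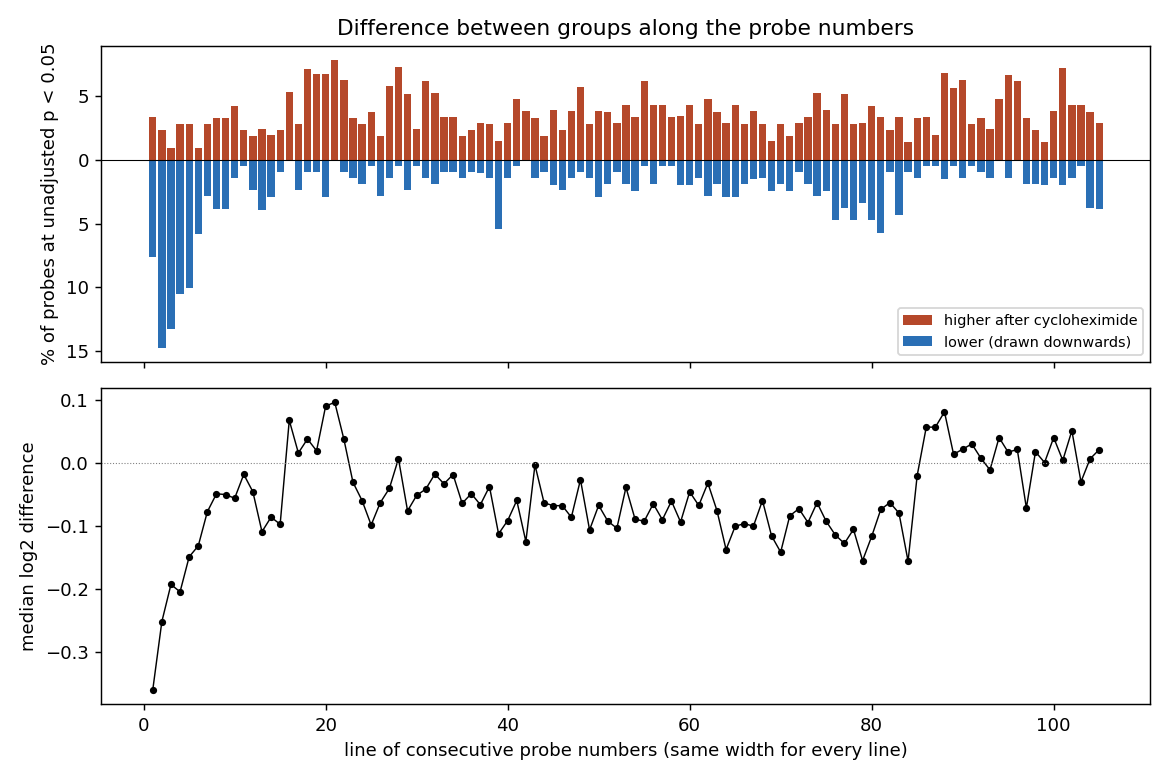
Share of probes at an unadjusted p under 0.05 (upper panel, in percent, lower probes drawn downwards) and median log2 difference (lower panel) for each of 105 lines of 215 consecutive probe numbers. The first 5 lines have a median difference of -0.22, against -0.05 elsewhere, and of -0.11 against -0.05 without array 3 of cycloheximide.

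The arrays of a group were not always closest to each other. Array 3 of cycloheximide correlated across probes at 0.909 with array 3 of strontium, and at 0.762 and 0.810 with arrays 1 and 2 of its own group. Arrays 1 and 2 of cycloheximide correlated at 0.953 with each other. The first principal component held 53.2% of the variance with scores of 75.5 and 65.8 for array 3 of cycloheximide and of strontium, and between -76.0 and 12.5 for the others. These scores follow the order of the spread within arrays: the interquartile range was 1.60 and 1.59 for these arrays, and 1.11 to 1.41 for the others. These correlations are across probes, which are not independent replicates. Without array 3 of cycloheximide 4242 probes were at an unadjusted p under 0.05, of which 1421 were higher and 2821 lower, and 0 passed the adjusted threshold.

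**Figure D3:**
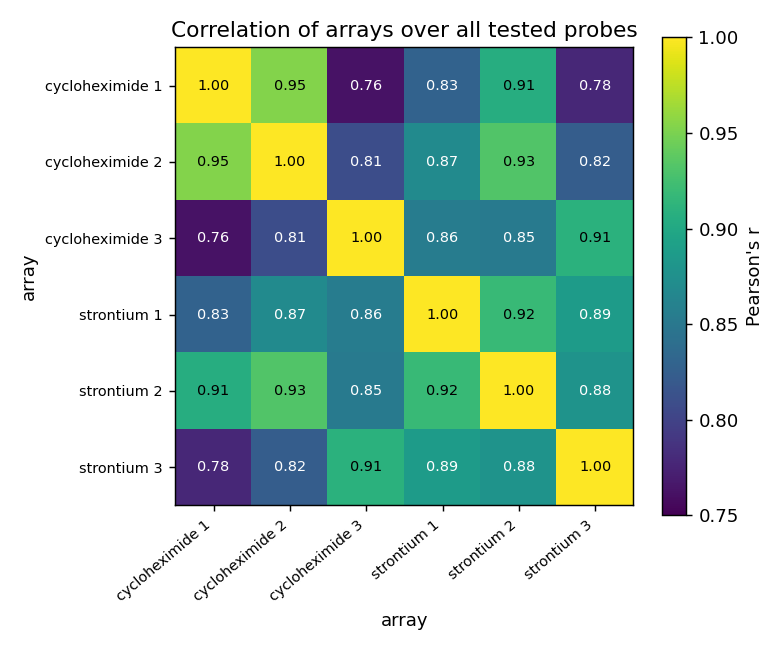
Pearson correlation of each pair of the 6 arrays over all tested probes, on a colour scale from 0.75 to 1. Array 3 of cycloheximide is closest to array 3 of strontium (0.909).

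Lists of genes fixed beforehand were compared to ask whether lineages, imprinted genes or cell functions moved together. Of the 30 lists, 0 passed camera's test, and the lowest adjusted p was 0.485. With an estimated correlation 0 lists passed (lowest adjusted p = 0.910), and by fry 0 passed (lowest adjusted p = 0.740). In the account of the lists each gene's value is the average of its probes, as in the tests, although the genes were picked by their probe with the smallest p. Over all 4742 genes 54.7% lay below 0, with a median difference of -0.03, which is the background for the counts of list members on each side of 0. Of the list members, 0 passed over all genes. Adjusted over the list alone, 1 passed: Polr1a, among 25 genes of ribosome biogenesis and the nucleolus, with a limma adjusted p of 0.0313. This adjustment was made within each of the 30 lists separately, with no correction over the lists, so a member can pass by chance.

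Among trophectoderm and blastocyst genes, 16 were measured, 9 below 0 and 7 above, with a median difference of -0.07. Tfap2a, a transcription factor of the trophectoderm lineage, was at 0.35 ± 0.17 after cycloheximide and 1.38 ± 0.43 after strontium, a difference of -1.02. Cdh1, the adhesion molecule of compaction, differed by -0.51 and Gata3 by -0.49. Of 12 genes of the primitive endoderm, 9 lay below 0, with a median of -0.29; Gata4 differed by -1.04 (SE 0.61) and Lama1 by -0.57. Lamb1, whose probe had the smallest p of that list, differed by 0.15 (SE 0.39), with 0.63 and -0.34 for its 2 probes. Of 13 pluripotency genes, 5 lay below 0, with a median of 0.08. The other 8 include Tdgf1, which was at the upper limit on all 6 arrays and so lies neither above nor below 0. Dppa3, whose ratio was at the upper limit on 1 array, differed by -0.49 (SE 0.43), a size that is therefore uncertain, and Tfcp2l1 by -0.21. Dppa2, with the smallest p of that list for 1 probe, differed by 0.13 (SE 0.21), and its probes by 0.52 and -0.26, the latter with 2 arrays at the limit. The camera adjusted p was 0.485 for the first of these lists, 0.485 for the primitive endoderm and 0.961 for pluripotency.

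Of 10 measured genes listed as expressed from the paternal copy, 9 lay below 0, with a median difference of -0.34 and a camera adjusted p of 0.485. The embryos arose without sperm, so neither group holds a paternal copy. The list includes Zim1 (difference -0.13), which in mouse is expressed from the maternal copy. Xist, the RNA that silences an X chromosome, was at 0.44 ± 0.33 after cycloheximide and 1.06 ± 0.20 after strontium; its probes differed by -1.14 and -0.10. Impact differed by -0.08 over its 5 probes, and by -0.60 for the probe with the smallest p. Of 7 maternally expressed genes, 5 lay below 0, with a median of -0.13; Copg2 differed by -0.79 and Gnas by 0.01, with -0.52 for its probe with the smallest p. Of 12 oocyte transcripts, 7 lay above 0, with a median of 0.10, and Dnmt1 differed by 0.38. Of 5 genes of the 2-cell embryo, Eif1a differed by 0.48 and Hspa8 by -0.28, with 1 of its 6 probes at exactly 0 on 5 arrays.

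Of 28 calcium signalling genes, 19 lay below 0 and 9 above; the median was -0.09 and the mean 0.04. Its 3 members at an unadjusted p under 0.05 were all higher: Plcd4, a phospholipase C (difference 2.06), Trpm7, an ion channel (1.31), and Ier2 (1.03). Over all 4742 genes, 203 were higher and 112 lower at this unadjusted p, so such genes leaned to the higher side in general. Slc8a1, a sodium and calcium exchanger, differed by -0.27. In the heat shock list Hspb1 differed by 0.68, Hspa4 by 0.46 and Dnajb6 by -0.41, with a list median of 0.07 over 15 genes and a mean of -0.07. Of 14 genes of the unfolded protein response, 9 lay above 0, with a median of 0.21; Eif2ak3 differed by 1.01 and Dnajb11 by 0.58. In the p53 list, Cdkn1a, an inhibitor of the cell cycle, differed by 0.65, Gadd45g by 0.38 and Sesn1 by -0.53, while the list's median was -0.10. Of 19 apoptosis genes, 10 lay below 0, with a median of -0.02; Bcl2 differed by -0.29, Cycs by -0.85, Pdcd4 by -0.94 and Bbc3 by 0.61. Of 12 oxidative stress genes, 9 lay below 0, with a median of -0.11, and Gsr differed by 0.96, Keap1 by 0.50 and Prdx1 by -0.49.

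Of 44 ribosomal protein genes, 29 lay below 0, with a median of -0.06; Rpl7a differed by 0.23 over its 12 probes, with 1.37 for the probe with the smallest p. Rpl29 differed by -0.49, with 1 of its 3 probes at exactly 0 on 3 arrays. Eif4g3 differed by 0.67 among 23 translation factors, whose median was 0.01. The median was 0.09 for ribosome biogenesis. Of 28 genes of oxidative phosphorylation, 18 lay below 0, with a median of -0.14, and Ndufs4 differed by -1.49 and Atp5b by 0.53. Glycolysis genes had a median of -0.14 and a mean of 0.00, with Ldhb at a difference of 0.80 and Ldha at -0.43. Acly differed by 0.62 and Fdft1 by -0.63 in the list of cholesterol and fatty acid synthesis, whose median was -0.02.

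Of 30 mitosis genes, 16 lay above 0, with a median of 0.11; Prc1 differed by 0.95 and Mad2l1 by 0.85. Cdc7, a kinase of replication origins, differed by 0.71 and Mcm3 by -0.43 in the DNA replication list, whose median was 0.02. Of 21 chromatin genes, 14 lay above 0, with a median of 0.17, and Smarca5 differed by -0.31 and Ehmt1 by 0.85. In the splicing list (median 0.08), Hnrnpd differed by 0.68 and Srsf6 by -0.67. Psmb9, a subunit of the immunoproteasome, differed by 1.27, with 1 of its probes at exactly 0 on 1 array; its list of proteasome and ubiquitin ligase genes had a median of 0.01. In the actin list (median -0.06), Actn4 differed by -0.43 and Rhob by 0.80. Signalling receptors and ligands had a median of 0.00, and Wnt9a differed by 0.31. That median is the value of Tdgf1, which was at the upper limit on all 6 arrays and so could show no difference.

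Markers of other cells did not pass the test either. The median difference was 0.07 over 5 cumulus and granulosa genes, 0.03 over 6 blood genes, -0.17 over 8 fibroblast genes and -0.30 over 9 adult organ genes. Gja1 differed by -0.65, S100a8 by 0.21, Col6a1 by 0.23, Mgp by -0.68 (SE 0.61), Syt1 by 0.45 and Tat by -0.51. Cyp11a1 was listed at exactly 0 on all 3 cycloheximide arrays for 1 probe, which is not a level. The camera adjusted p was 0.901 for the first 3 of these lists and 0.751 for the adult organs.

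**Figure D4:**
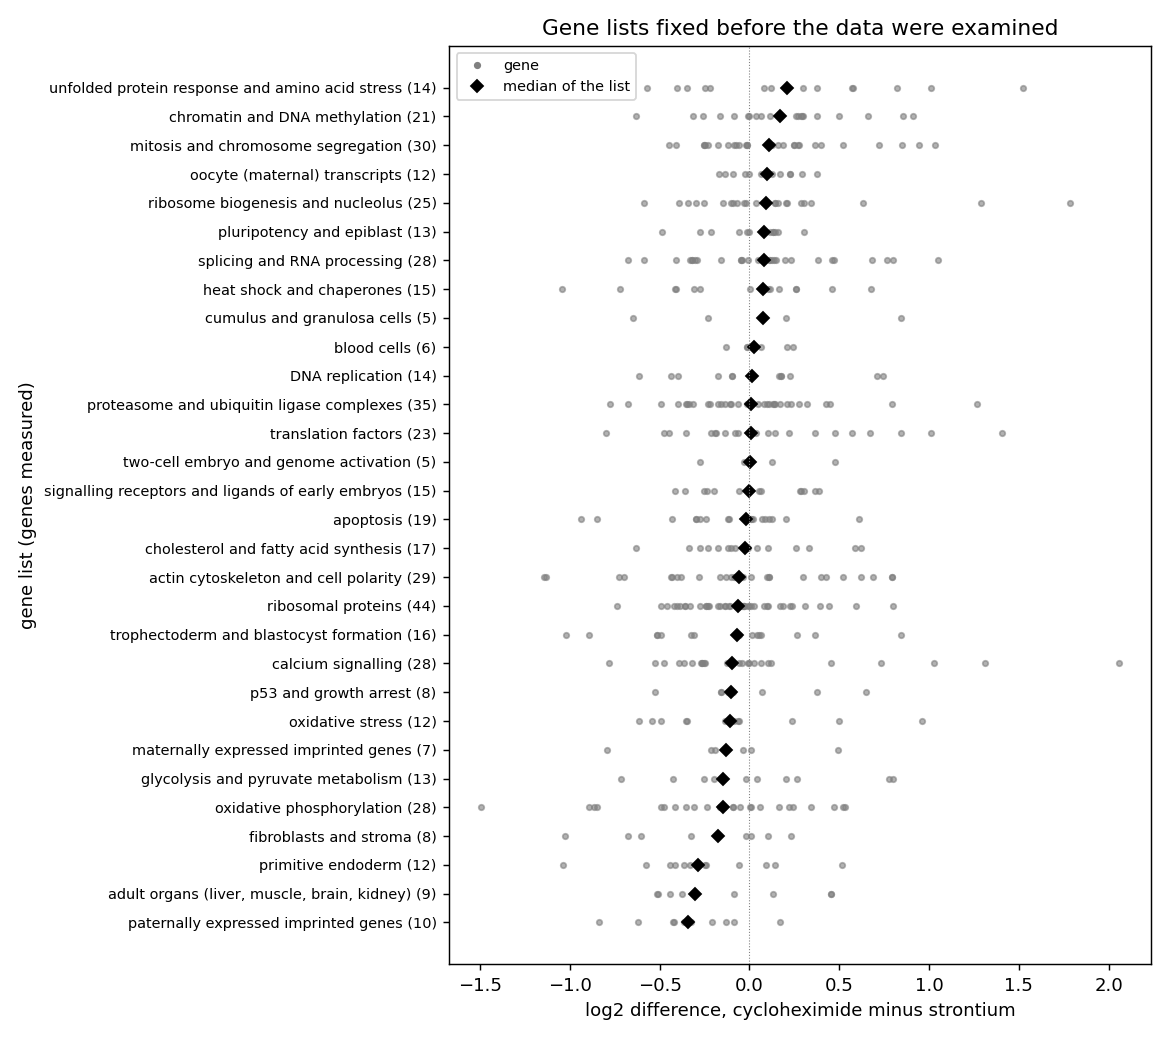
Log2 difference, cycloheximide minus strontium (horizontal axis), of each measured gene (grey dots) in the 30 lists, with the median of each list (diamonds) and the number of genes in brackets. List medians lie between -0.34 and 0.21, and 0 lists passed camera's test.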

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

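The corrections for position and the fits of all probes were chosen after seeing the data. The counts of 0 higher and 0 lower probes held under every alternative without array weights. With array weights 224 were higher and 135 lower, and with all 22132 probes kept and array weights 12 higher and 3 lower. The weights gave array 2 of cycloheximide 22.6 and array 3 of that group 0.16, the estimate stopped before it converged, and leaving 211 probes in or out moved the calls from 15 to 359; the cause was not tested. With all probes kept and no weights, 0 passed (lowest adjusted p 0.286, with 1434 at an unadjusted p under 0.05). The replicate block gave 0 and 0 calls and 2086 probes at an unadjusted p under 0.05, against 1319. Not every array correlated best with its own number. The deviations of same-numbered arrays correlated at 0.056, 0.379 and 0.501, and those of cycloheximide 1 and strontium 2 at 0.457. Leaving out 1 array gave 0 calls each time, with 748 to 1393 probes unadjusted except 4242 without array 3 of cycloheximide. The list tests gave 0 calls under every alternative run, with a lowest adjusted p of 0.0925 without that array. Of 2394 alternative values of 137 named genes, 23 changed sign in 15 genes, 25 passed the threshold in 21 genes, all under array weights, and none passed otherwise. Of 480 alternative values of lists, 43 changed direction. The oocyte list lay above both other lists on 4 arrays, or 5 with each probe as a member. Signal over background was not analysed here.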

Other observations

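Against the reference RNA, embryos of both groups shared strong differences in ratio. These genes were chosen after their values were seen, and without exchanged dyes a bias of the dye stays open for each. Embryo RNA was amplified in 2 rounds and reference RNA in 1 on every array. An effect of the rounds on a probe therefore cannot be told apart from a difference in level. A ratio at its limit is a reduced value, so a mean that holds one is too small in size and its SD is not the true spread. Tdgf1, a co-receptor of Nodal, was at the upper limit of the ratio on all 6 arrays. Dppa3, a maternal and pluripotency gene, was at 5.75 ± 0.80 after cycloheximide and 6.24 ± 0.37 after strontium (SD, n = 3), with 1 array at the limit. Dppa2 was at 6.17 ± 0.47 and 6.43 ± 0.21 for its higher probe, with 2 arrays at the limit, and at 2.14 ± 0.30 and 1.62 ± 0.41 for its other probe. On the reference side, S100a6 was at the lower limit on all 6 arrays, Sparc, a matrix protein, at -5.73 ± 0.16 and -5.82 ± 0.18, and Col1a1, a collagen of fibroblasts, at -5.51 ± 0.99 and -4.91 ± 0.89, with 1 array at the limit.

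Of the tests that follow, those of splits, of array ranges, of limited ratios, of crossed labels and of the position without each array were chosen after the result was seen. For stage, stromal RNA, crossed labels and the response of genes by position, the rule for excluding the explanation was made stricter after the values were seen; the earlier rules would have excluded all 4.

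The 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 1319 probes at an unadjusted p under 0.05, and 3 of the 10 splits gave as many, the highest other giving 5926. That split sets arrays 1 and 2 of cycloheximide and array 2 of strontium against the rest and has several times the real count, which points to a structure of the samples. For gene lists the real count was 0, which all 10 splits reach by construction, so the comparison says nothing; the highest other was 1. With array weights, other splits called 6284 and 4080 probes against 359 for the real one.

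Array 3 of cycloheximide correlated better with array 3 of strontium than with its own group, by 0.0997, and both had the widest interquartile range (1.60 and 1.59, against 1.11 to 1.41) and 130 and 92 values at the lower limit of the deposited ratio, against 4 to 40. Both carry number 3 in the labels, and whether this number marks a shared culture or day was not tested and stays open. A Pearson correlation does not change when an array is rescaled, so equal ranges were bound to leave this gap nearly the same. After quantile normalization, with a range of 1.35 on each array, the gap was 0.0899 (95% bootstrap interval over probes 0.0841 to 0.0963). The first component, which ranges can affect, then held 51.2% of the variance and kept the order of the arrays. This argues against array ranges as the whole cause of that component. Without limited or unset ratios the gap was 0.107, which argues against these as its cause. A narrowing of ratios that depends on signal stays open, as no intensities were used. Crossed labels of cycloheximide 3 and strontium 2 stay open, as the correlations point both ways and have no spread between arrays. Strontium 1 correlated better with strontium 2, by 0.0312, which goes against an exchange. Strontium 2 itself correlated best with cycloheximide 2 (0.933), which goes with an exchange. Its correlation was 0.906 with cycloheximide 1, and 0.918 and 0.878 with strontium 1 and 3. The split with 5926 probes is the exchanged grouping, with 2417 probes at an adjusted p under 0.10 and 0 under 0.05. It sets the arrays with scores below 0 on the first component (-76.0, -56.2 and -21.7) against those above 0 (12.5, 65.8 and 75.5). Its count therefore follows that component and cannot tell an exchange from another cause of it. Embryo stage and RNA from cumulus or stromal cells stay open: on array 3 of cycloheximide against arrays 1 and 2, the oocyte list differed by 0.17 (random lists of its size -0.39 to 0.56), trophectoderm by 0.13 (-0.32 to 0.55), cumulus by 0.34 (-0.79 to 0.88) and fibroblasts by 0.0872 (-0.71 to 0.93). Oocyte and trophectoderm lists did not lie on opposite sides, as a stage difference was predicted to give, but a shift within these spans would go unseen in lists of 5 to 16 genes, so the rules set beforehand (a median within the span excludes a stage difference, a fibroblast shift under 0.5 stromal RNA) were not applied.

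Probes lower after cycloheximide crowded at the lowest probe numbers: 118 of 508 lay in the first 5 lines, which hold 4.78% of probes; this was noticed while the named lower genes were read, and the line width of 215 (autocorrelation 0.083), the number of lines and the blocks were chosen from the data; a step of 7 numbers gave a higher autocorrelation, 0.089. The numbers could not be set against real rows and columns, so a place on the array is a candidate explanation whose link to the numbers is unverified: other probes of the same 97 genes, placed elsewhere, had a median difference of -0.018, against -0.035 for all such probes there and -0.136 at the lowest numbers. A response of the genes placed there stays open: the interval of their other probes, -0.072 to 0.049, lies above -0.136 and so meets the rule set beforehand for excluding it, but that rule takes -0.136 as fixed, whose own interval is -0.284 to -0.035. The gap of 0.119 had a bootstrap interval of 0.00 to 0.29, with the lower bound below 0 in 5 of 6 repeats of the draw, and after centring by blocks 5.82% of these probes were still lower, against 1.71% elsewhere. Leaving out array 3 of cycloheximide weakened the pattern most: the median difference at the lowest numbers lay 0.17 below that elsewhere with all arrays, 0.06 without this array, and 0.16 to 0.23 without any other. Its median deviation from each probe's mean was -0.221 there and 0.070 elsewhere. Cycloheximide 1 and 2 were at -0.018 and -0.003 there, against -0.022 and -0.040. The strontium arrays lay higher there (0.152, 0.087 and 0.166, against 0.064, -0.003 and 0.045), although a low array 3 itself raises the deviations of the others.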
